A study of Mus musculus with 3 samples.

How the data were processed

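The series holds single-cell RNA sequencing of kidney from wild-type mice before and after systemic infection with the yeast Candida albicans. There were 3 libraries, labelled naive, day 2 and day 6, 1 per group, each made from 3 kidney tissues per the labels. Tissue was minced and digested with collagenase II, red cells were lysed, and CD45-positive cells were enriched on magnetic beads, per the labels' protocols. Libraries were made with the 10x Genomics Chromium 3′ v3.1 chemistry, which counts the 3′ ends of polyadenylated transcripts by unique molecular identifier (UMI). The series' design text mentions more samples than these 3; others were not analysed here.

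The deposited matrices hold raw UMI counts per gene and cell barcode, as whole numbers with no normalization. Per the file headers they were written by cellranger-8.0.1, and per the submitters' processing notes the tools were Cell Ranger 9.0.0, Seurat 4.0.0 and R 4.0.3 with the mouse build GRCm39. What Seurat was used for, the gene annotation release and the cell calling settings were not given in the sources used here. Each library's tables were present in 2 copies whose contents were identical apart from comment lines, and 1 copy was used. The tables list 33696 genes and 13660 naive, 13521 day 2 and 15756 day 6 barcodes, with totals of 90587361, 108954471 and 107914560 UMIs. No barcode had fewer than 500 UMIs. The genome at hand was of an older mouse build, so no coordinates are given, and gene symbols and identifiers are those of the deposited tables.

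Cells with at least 200 genes and at most 20% mitochondrial UMIs were kept. Under 200 genes were 340, 94 and 82 barcodes of the naive, day 2 and day 6 libraries, and over 20% mitochondrial UMIs were 1185, 252 and 406, which is 8.67%, 1.86% and 2.58%. Doublets were called per library by an own implementation of the Scrublet procedure with 2 simulated doublets per cell and exact neighbours, with the threshold at the minimum between the modes of the simulated scores. It removed 537, 628 and 625 cells (4.305%, 4.733% and 4.072%). This left 11938 naive, 12640 day 2 and 14724 day 6 cells, with median UMI counts of 5512, 6076 and 4587.

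Counts were scaled to 10000 per cell and log transformed. The 3 libraries were clustered together without batch integration on 2000 variable genes, 30 principal components and 20 nearest neighbours, with the Leiden algorithm at resolution 1. This gave 34 clusters. A cluster was named from 25 fixed marker sets when at least 3 markers and a share of at least 0.4 of the set were each in at least 15% of its cells and at least 2-fold above the median cluster, and when its 10 leading genes (genes in at least 10% of its cells, ranked by fold with 5 CPM added) held no more markers of another class than of its own. A cluster of low UMI count also needed an own marker among its leading genes. In all, 30 clusters in 14 classes were named and 4 stayed unnamed. All class names stand for cells that resemble the type by these markers. Monocyte and macrophage clusters were joined as mononuclear phagocytes, and tubule stands for all tubular clusters. The markers Tcrg-C1, Tcrg-V6 and Cd163l1 and the list members Aldoa, Atp5f1a and Atp5f1b did not match exactly 1 gene by symbol and were left out, and 26 symbols were shared by 2 genes.

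UMIs were summed per class and library and divided by the class total to give counts-per-million values (CPM). Cells are not replicates and each group had 1 library, so no test across samples was run. Intervals are exact at 95%: binomial for a share, Poisson for a level and conditional binomial for a ratio of levels; a difference of shares has its own 95% interval. All of them cover counting error only. A class was compared when it had at least 50 cells in both libraries. Where 1 library had 0 counts the ratio was taken against a floor of 3 counts per library and written as a lower bound. Shares of cells with a UMI were taken after thinning each cell to 1000 UMIs, leaving out shallower cells. The B class served as background for these shares.

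There were 20 gene lists. Of these, 1 list is not reported here; it was left out of the counts of list medians under alternatives but stays in the numbers of lists outside the middle of random lists. Some single genes are not reported by name but stay in the medians of their lists. The other lists are IL-1 family and inflammasome, Dectin and CARD9 signalling, C1q and C1q receptors, chromatin repressors and histone demethylase, neutrophil chemoattractants and growth factors, monocyte and lymphocyte chemoattractants, interferon response, granule and antimicrobial, MHC class II presentation, tissue-repair macrophage, glycolysis and hypoxia, oxidative phosphorylation, cytotoxic effector, lymphocyte activation and checkpoint, naive and central memory T, cell cycle, immediate early and heat shock, proximal tubule transcripts as background RNA, and tubular injury. Members with at least 20 UMIs in 1 of the 2 libraries were measured. A member counted as higher or lower when its CPM ratio was at least 2-fold with an interval that excluded 1. The median log2 ratio of a list was set against 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. The median gene of a class shifted between libraries, so list medians are given relative to it.

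Genes were named by size: in each comparison and class (neutrophil, mononuclear phagocyte, T) the 5 with the highest and the 5 with the lowest CPM ratio, a count under 3 taken as 3, among genes with at least 100 CPM and 30 UMIs in the higher library, an interval that excluded 1, and at least 0.2 of the highest CPM of any named class in that library. Only classes with at least 50 cells in that library counted for this share, which left out the 40 tubule cells of day 6. Mitochondrial, ribosomal protein, predicted and clone genes, antigen receptor segments, haemoglobin genes, Xist, Tsix and Y-linked genes were left out. List members were named to describe their list, without the minimum CPM or the 0.2 share. Ratios and list medians within single clusters were taken where a cluster had at least 50 cells in both libraries, and were added after seeing the data.

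The comparisons, marker sets, lists, named-gene rule, filters and most alternatives were fixed before the data were examined. Chosen after seeing the data were the naming of clusters by fold over the median cluster with the marker share of 0.4, the doublet implementation, and the alternatives that left out low-UMI clusters, counted unnamed clusters with T or mononuclear phagocyte markers, or used macrophage clusters alone. The other alternatives were at least 500 genes, at most 10% mitochondrial UMIs, doublets kept, resolution 0.5 and 2, separate clustering of the libraries, median-of-ratios scaling, subtraction of the B cell level, thinning to 500 UMIs, list minimums of 1 and 100 UMIs and no minimum CPM for named genes.

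The ratio, interval and list steps were tested on simulated counts with 200 changed genes. Filtering, doublet calling, clustering and naming were not. In the simulated comparison of mononuclear phagocytes on day 2 with naive, over 15947 genes, 98.5% of genes changed 4-fold and 92.5% of those changed 2-fold had an interval that excluded 1. In the smaller neutrophil class on day 6 against naive, over 10456 genes, these shares were 86.4% and 62.7%. Among unchanged genes they were 4.6% and 3.84%. The counts were Poisson draws from 1 pooled profile, as the intervals assume, so a low share among unchanged genes was built in. Variation between cells, animals or preparations was not simulated, so these shares are not rates of false calls between single libraries. The analysis used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scikit-image 0.26.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.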

Results

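The deposited counts came from kidney immune cells of wild-type mice that were uninfected (naive), or 2 or 6 days into systemic infection with Candida albicans, a yeast that invades the kidney from the blood. The libraries held 13660 naive, 13521 day 2 and 15756 day 6 barcodes with totals of 90587361, 108954471 and 107914560 UMIs. After filtering, 11938, 12640 and 14724 cells were kept. Each group had 1 library, so no difference between groups was tested or has a replicate check, and all intervals are 95% intervals that cover counting error only. The series title concerns the cytokine interleukin-1β, the mitochondrial protein C1QBP, which also binds complement C1q, and Dectin-1, the receptor for fungal β-glucan encoded by Clec7a. The comparisons address how the kidney's immune cell classes, and these transcripts within them, differed at each day of infection.

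Neutrophils took a larger share of cells at each day of infection, with 3.76% (3.43 to 4.12) of naive, 9.17% (8.67 to 9.69) of day 2 and 27.5% (26.8 to 28.2) of day 6 cells. Their share was 2.44-fold higher on day 2 and 7.31-fold higher on day 6 than in naive kidney. T cells made up 6.87% (6.42 to 7.34), 17.1% (16.5 to 17.8) and 20.5% (19.8 to 21.1) of the naive, day 2 and day 6 cells. Mononuclear phagocytes, the joined monocyte and macrophage clusters, were the most numerous class in each library, with 51.8% (50.9 to 52.7), 60.2% (59.3 to 61.1) and 38.3% (37.5 to 39.1). B cells were 5.87-fold lower on day 2, at 1.88% (1.65 to 2.13) against 11.0% (10.4 to 11.6) in naive kidney, and 4.57-fold lower on day 6.

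Natural killer (NK) cells held 1.79% (1.56 to 2.05) of naive, 2.56% (2.29 to 2.85) of day 2 and 0.924% (0.776 to 1.09) of day 6 cells. Group 2 innate lymphoid cells (ILC2) were 10.6-fold lower on day 2, at 0.134% (0.0784 to 0.215) against 1.42% (1.22 to 1.65), and 7.77-fold lower on day 6. Migratory dendritic cells were 3.47-fold higher on day 2, at 0.815% (0.666 to 0.987) against 0.235% (0.156 to 0.339), and 2.23-fold higher on day 6. Of the other dendritic cells, type 2 conventional cells (cDC2) held 4.03%, 2.87% and 2.09%, type 1 conventional cells (cDC1) 1.94%, 0.696% and 0.951%, and plasmacytoid cells 1.26%, 0.427% and 0.666% of the naive, day 2 and day 6 libraries. Plasma cells held 0.687%, 0.562% and 0.537%. Tubule cells lie outside the CD45 bead selection, which sets their share, and made up 4.98%, 0.767% and 0.272%.

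**Figure D1:**
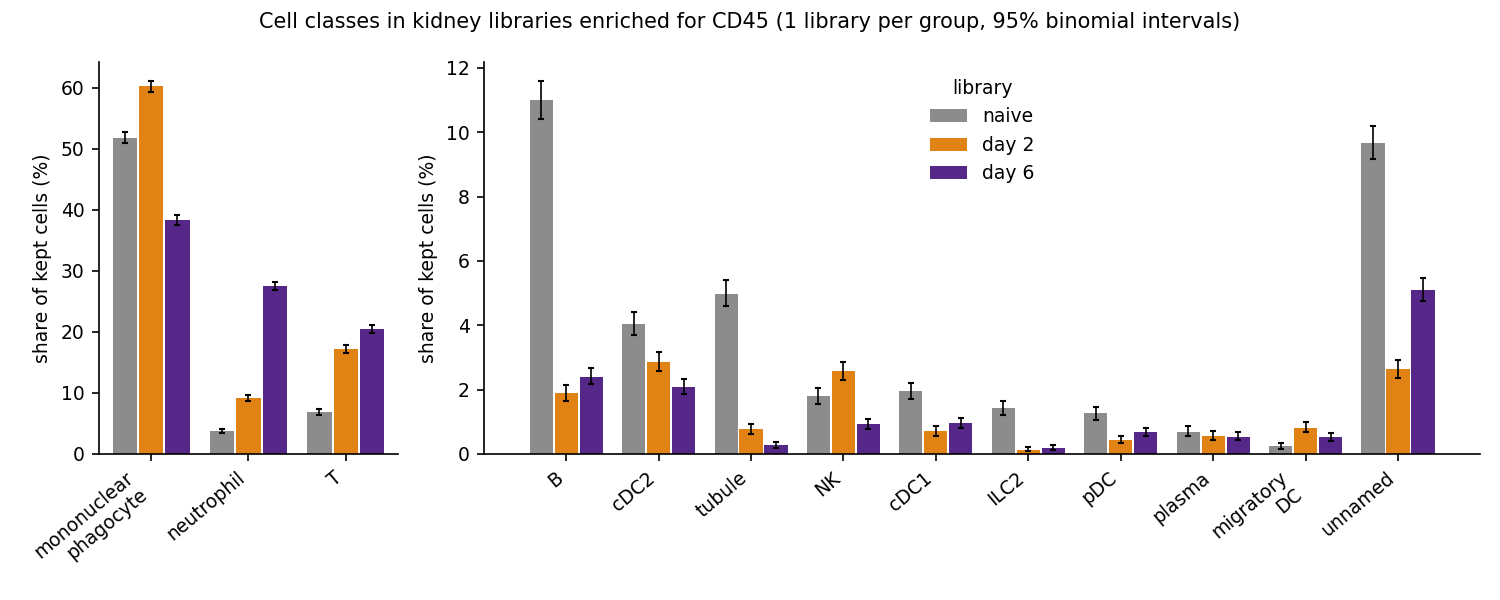
Share of kept cells in percent (vertical axis, from 0) of each cell class in the naive, day 2 and day 6 libraries, 1 library per group; bars are shares and lines 95% binomial intervals. Neutrophils went from 3.76% in naive to 27.5% in day 6 kidney and B cells from 11.0% to 2.4%.

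Shares of 1 library add up to the whole, so a larger class lowers the others. Among named immune cells alone, mononuclear phagocytes held 61.0% (60 to 61.9), 62.4% (61.5 to 63.2) and 40.5%, neutrophils 4.43%, 9.5% and 29.1%, and B cells 13%, 1.94% and 2.54%. The mononuclear phagocyte difference of 8.43 points (7.19 to 9.67) between day 2 and naive was −18.9 points when the libraries were clustered separately, where 27.0% of day 2 cells stayed unnamed. It was 6.91 points when unnamed clusters with macrophage or monocyte markers were counted there. Its day 6 difference of −13.5 points was −0.057 at resolution 2, where 24.4% of naive cells stayed unnamed. The T cell difference on day 2 of 10.3 points (9.48 to 11.1) was 3.9 when the unnamed clusters 13 and 16, which carried T markers, were counted. Its day 6 difference of 13.6 points was 2.01 with separate clustering. From day 2 to day 6 the T share differed by 3.31 points (2.39 to 4.24), and by −4.91 with separate clustering. With separate clustering 12.9% of naive cells were named T, and no NK cluster was named in the naive and day 6 libraries, so the NK cells' differences of 0.763 points on day 2 and −0.869 on day 6 have no value there. Unnamed cells made up 9.68%, 2.63% and 5.11% of the libraries. Among these, cluster 13, with the NK marker Klre1 among its leading genes, held 3.42%, 1.51% and 3.86%. Cluster 30, kept out of the classes by a threshold set after seeing the data, held 0.888%, 0.119% and 0.122%.

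Il1b (ENSMUSG00000027398), the gene of interleukin-1β, was highest in neutrophils, at 9629 CPM in naive, 11851 on day 2 and 13613 on day 6. The infected libraries were 1.23-fold (1.21 to 1.25) and 1.41-fold (1.39 to 1.44) above naive. These folds also hold a different mix of clusters. Il1b was 9365, 16368 and 13785 CPM in naive, day 2 and day 6 cells of cluster 11, which held most naive neutrophils, and 14259, 18446 and 16334 CPM in cluster 3. Cluster 9, with 615 of 1159 day 2 but fewer than 50 naive neutrophils, stood at 6396 and 4496 CPM on day 2 and day 6. In mononuclear phagocytes it was 468 CPM in naive, 1025 on day 2 and 841 on day 6. This was 2.19-fold (2.15 to 2.23) and 1.8-fold (1.77 to 1.83) above naive, and day 6 stood at 0.82 (0.811 to 0.83) of day 2. Within single mononuclear phagocyte clusters with at least 50 cells in both libraries, the day 2 ratio went from 1.07 (0.975 to 1.18) in cluster 2 to 3.38 (2.82 to 4.06) in cluster 20. The day 6 ratio went from 1.04 (0.956 to 1.14) in cluster 2, which held 2159 of 5636 day 6 cells, to 4.58 (4.27 to 4.91) in cluster 12. Cluster 0, with 4434 of 6180 naive cells, stood at 502 CPM in naive and had too few day 2 cells for a ratio. Clusters 1 and 4 held 2319 and 1941 of 7609 day 2 cells but 30 and 0 naive cells. They stood at 725 and 1589 CPM on day 2. Cluster 4 held 40816 of the 74412 Il1b UMIs of day 2 mononuclear phagocytes. The class ratios therefore also hold a different mix of clusters. Mononuclear phagocytes contributed 46.2%, 61.9% and 20% of all Il1b UMIs of the naive, day 2 and day 6 libraries, and neutrophils 44.8%, 31.8% and 75.2%. Il1b in cDC2 was 4.07-fold (3.78 to 4.38) higher on day 2 and 3.66-fold (3.4 to 3.95) higher on day 6, and in cDC1 4.99-fold and 3.0-fold higher. B cells, which served as the background class, held 42.5, 441 and 129 Il1b CPM, on day 2 more than the 319 of cDC1, and T cells 49.1, 91 and 128 CPM. With the B cell level subtracted, the log2 ratio of Il1b in mononuclear phagocytes on day 2 over naive was 0.46 in place of 1.13, and that of day 6 over day 2 was 0.29 in place of −0.29. This subtraction was by CPM. Free RNA would add a like number of UMIs per cell, and day 2 mononuclear phagocytes were deeper than B cells (median 9248 against 2859 UMIs). The subtraction therefore takes too much from them, and the smaller ratio and changed sign may come from it.

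Between days, the median gene of a class shifted by −0.25 and −0.17 (log2, day 2 and day 6 over naive) in neutrophils, −0.35 and −0.16 in mononuclear phagocytes and −0.27 and −0.09 in T cells, and from day 2 to day 6 by 0, 0.18 and 0.15. Folds of single genes are ratios of CPM, and medians of gene lists are given relative to the median gene of the class. Relative to it, Il1b in mononuclear phagocytes was 2.8-fold higher on day 2 and 2.0-fold higher on day 6, and in neutrophils 1.46-fold and 1.59-fold higher. Genes named by size had at least 0.2 of the highest CPM of any class with at least 50 cells, but members of gene lists were named without this minimum. In the library where they were higher, the named members that stood under it included C1qa, Ezh2, Mki67 and Ccnb2 in neutrophils. In mononuclear phagocytes they included Il1b, Il1rn, Il1a, Clec4d, Clec4e, Gbp2, Ccl5, Lcn2 and Spp1 on day 2. On day 6 they included Il1b, Il1rn, Slpi, Cxcl3 and Egr1 there. Others were Oasl1, Isg15, Ccr7 and Il2ra in T cells, Gzmk in NK cells and Lcn2 and Cd44 in tubule cells. The tubule transcripts Miox and Lrp2 stood under it in immune cells. For example, Il1rn on day 2 was 152 CPM in mononuclear phagocytes and 1720 in neutrophils. Free RNA from other classes was not excluded for them.

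After thinning to 1000 UMIs, 27.7% (26.5 to 28.8) of naive, 44.1% (42.9 to 45.2) of day 2 and 34.8% (33.5 to 36.1) of day 6 mononuclear phagocytes had an Il1b UMI, against 4.14% (3.11 to 5.39), 16.0% (11.5 to 21.5) and 10.3% (7.25 to 14.0) of B cells. Unthinned shares were 59.9%, 77.0% and 67.8% in mononuclear phagocytes and 13.3%, 29.5% and 28.8% in B cells. Median depths were 5730, 9248 and 7952 UMIs in mononuclear phagocytes and 3961, 2859 and 3718 in B cells. As too shallow, 525, 448 and 416 mononuclear phagocytes and 57, 12 and 13 B cells were left out. Neutrophils had an Il1b UMI in 95.2%, 91.2% and 93.7% of thinned cells and in 95.1%, 94.6% and 96.0% unthinned. Their median depths were 3936, 2732 and 2836 UMIs, with 52, 77 and 426 cells left out.

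C1qbp (ENSMUSG00000018446) in mononuclear phagocytes was 44.6 CPM in naive, 85 on day 2 and 75.5 on day 6. Its level was 1.9-fold (1.8 to 2.01) and 1.69-fold (1.6 to 1.79) above naive, with day 6 at 0.889 (0.853 to 0.925) of day 2. Within single clusters of the class, C1qbp was 1.34-fold to 2.75-fold higher on day 2, with an interval above 1 in 4 of 6, and at 0.802 to 2.01 of naive on day 6, with an interval above 1 in 4 of 7. The gene was 4.3-fold (3.14 to 5.97) higher on day 2 in plasma cells, 1.96-fold (1.46 to 2.61) in B cells, 1.93-fold (1.65 to 2.25) in cDC2 and 1.3-fold (1.14 to 1.49) in T cells. Neutrophils held 11.1, 9.91 and 6.29 C1qbp CPM from 20, 32 and 74 UMIs. Their day 2 ratio of 0.895 (0.496 to 1.65) included 1 and lay above 1 relative to the median gene, and their day 6 ratio was 0.567 (0.342 to 0.982). With the B cell level subtracted, the log2 ratio of C1qbp in mononuclear phagocytes on day 6 over naive was 2.11 in place of 0.76, and that on day 6 over day 2 was 1.6 in place of −0.17. In T cells C1qbp on day 6 over naive was −0.38 in place of 0.31 with this subtraction. B cells also express C1qbp, so they are not a class that lacks it. The limit of subtraction by CPM given for Il1b also holds here. At 1000 UMIs, 4.0% (3.5 to 4.54), 7.32% (6.72 to 7.95) and 6.0% (5.37 to 6.67) of the same mononuclear phagocytes had a C1qbp UMI, against 2.95% (2.08 to 4.04), 4.89% (2.47 to 8.58) and 3.52% (1.83 to 6.07) of B cells. Unthinned shares were 21.8%, 43.6% and 35.6% against 13.5%, 21.5% and 16.1%. In each library the thinned intervals of both classes overlapped.

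Clec7a (ENSMUSG00000079293) in mononuclear phagocytes was 202 CPM in naive, 376 on day 2 and 489 on day 6. This receptor gene was thus 1.86-fold (1.82 to 1.91) and 2.42-fold (2.36 to 2.49) above naive in a class whose clusters differed between libraries. Within clusters Clec7a went both ways on day 2. It was lower than in naive cells in clusters 10 (205 against 247 CPM) and 12 (188 against 386), alike in cluster 2 (164 against 170) and higher in clusters 5 (292 against 123), 17 (192 against 105) and 20 (498 against 303). On day 6 it was also lower in cluster 12 (338 CPM). In neutrophils Clec7a was 864, 559 and 940 CPM, so that day 2 stood at 0.647 (0.604 to 0.693) and day 6 at 1.09 (1.03 to 1.15) of naive. These ratios also hold a different mix of clusters. Clec7a was 869, 571 and 875 CPM in naive, day 2 and day 6 cells of cluster 11 and 951, 673 and 1064 in cluster 3. Cluster 9, with 615 of 1159 day 2 neutrophils, stood at 490 CPM on day 2 and 620 on day 6. In cDC2 Clec7a was 1.96-fold (1.75 to 2.19) and 2.68-fold (2.4 to 2.98) higher. Mononuclear phagocytes contributed 74.0%, 88.7% and 64.8% of all Clec7a UMIs of the libraries. At 1000 UMIs, 15.4% (14.5 to 16.4), 25.9% (24.9 to 26.9) and 27.4% (26.2 to 28.6) of mononuclear phagocytes had a Clec7a UMI, against 1.19%, 4.0% and 2.93% of B cells. Neutrophils had one in 49.6% (44.6 to 54.7), 36.0% (33.2 to 39.0) and 52.1% (50.5 to 53.7). Unthinned shares were 49.7%, 67.7% and 66.7% in mononuclear phagocytes, 78.8%, 57.3% and 72.8% in neutrophils and 4.8%, 12.2% and 8.47% in B cells, with the same cells left out as for Il1b.

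**Figure D2:**
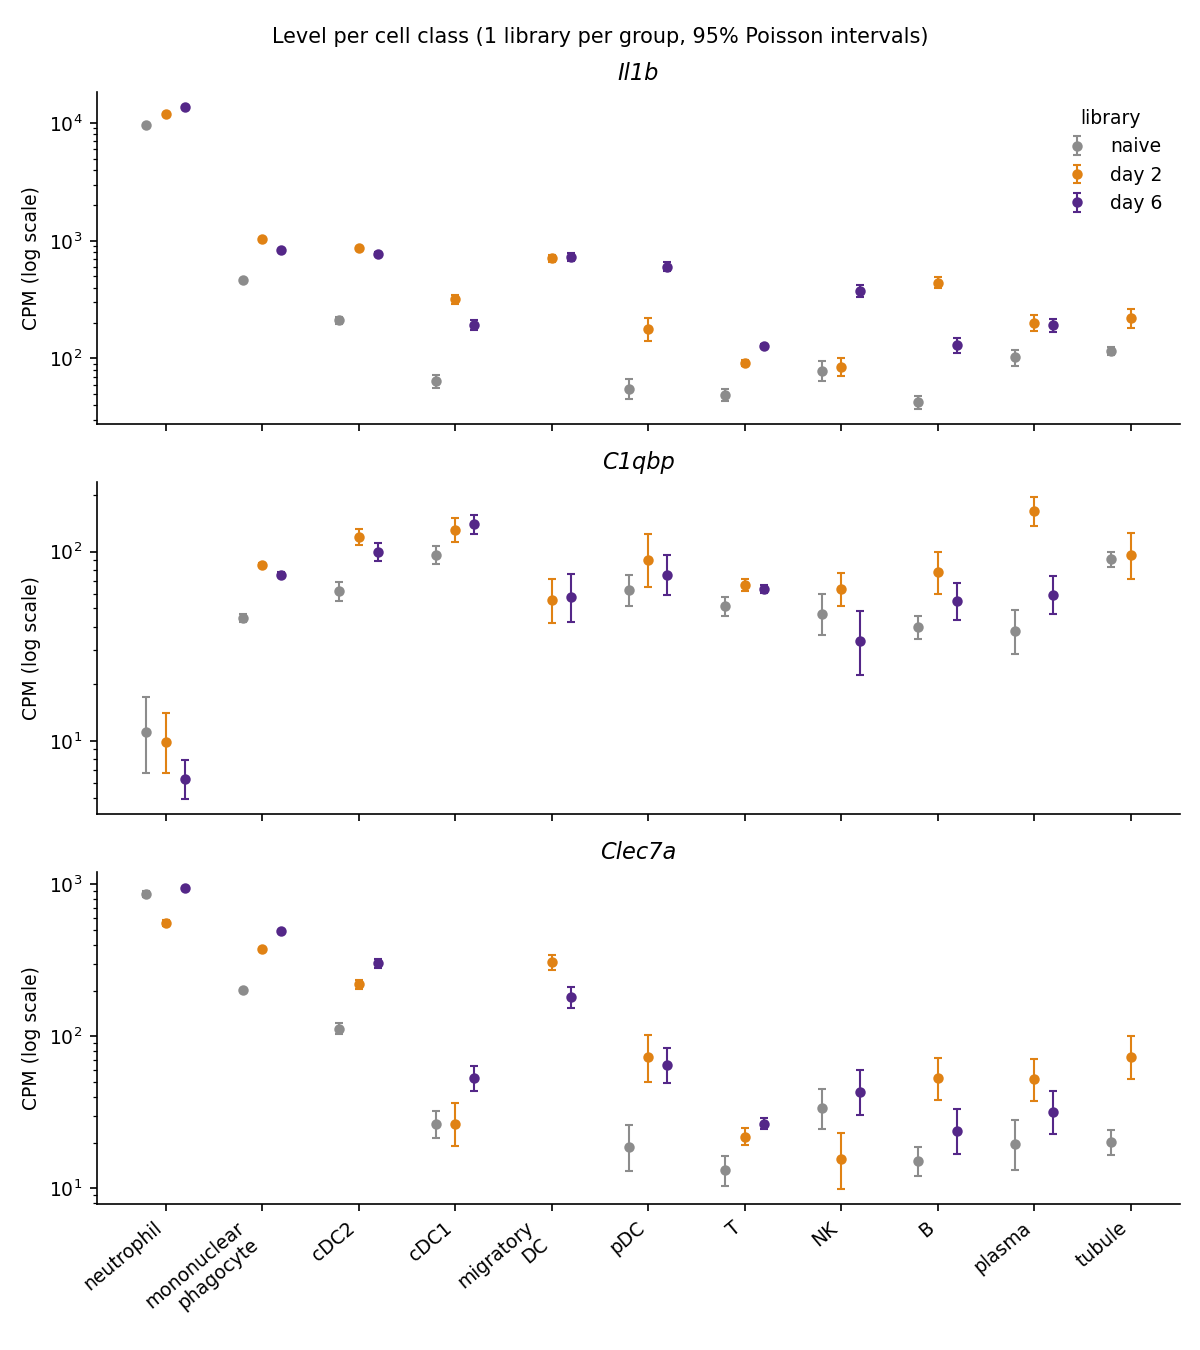
Level of Il1b, C1qbp and Clec7a (1 panel each) in CPM on a log axis, by cell class with at least 50 cells, in the naive, day 2 and day 6 libraries; points are levels and lines 95% Poisson intervals. Il1b stood at 9629 to 13613 CPM in neutrophils, and C1qbp in mononuclear phagocytes at 44.6 CPM in naive and 85 on day 2.

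Neutrophils on day 2 held more chemoattractant, interferon response and glycolysis transcripts than in naive kidney and fewer of the granule protein genes Camp, Ngp and Ltf. The 5 genes with the highest ratio were Saa3, an acute-phase serum amyloid A (450-fold, 80.5 to 17778, from 1 naive UMI), the interferon-induced chemokine Cxcl10 (149-fold, 87.1 to 280), Il1a, the gene of interleukin-1α (119-fold, 57.5 to 296), Ly6i (81.4-fold, 47.5 to 153) and the interferon-induced GTPase Gbp5 (47.7-fold, 25 to 105). The 5 with the lowest ratio were Camp, which encodes cathelicidin (58.1-fold lower, 46.2 to 74.1), the granule protein gene Ngp (22.3-fold, 19.7 to 25.4), Cntn5 (16.2-fold, 15.3 to 17.1), Ltf, which encodes lactoferrin (11.8-fold, 9.59 to 14.6), and Acpp (11.2-fold, 7.96 to 16.3). Cntn5, which encodes a neural adhesion molecule, was present at 26.9 to 34.2 UMIs per cell in all 12 naive classes measured. The log2 ratio of Cxcl10 was 4.42 in place of 7.22 with separate clustering. Most naive neutrophils were in cluster 11 (331 of 449 cells), whereas clusters 9 and 3 held 615 and 364 of the 1159 day 2 cells and 873 and 2206 of the 4050 day 6 cells. Il1r2 was also among the leading genes of cluster 3, Il1rn of cluster 9, and S100a8, S100a9 and Lcn2 of cluster 11.

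Among gene lists in day 2 neutrophils, 12 of 12 measured interferon response genes were at least 2-fold higher, with a median log2 ratio of 2.25 at percentile 100 of random lists. Among them were Gbp2 (17.5-fold, 13.8 to 22.4), Igtp (11.3-fold, 7.56 to 17.6) and Isg15 (4.11-fold, 3.68 to 4.59). All 7 measured neutrophil chemoattractants and growth factors were higher, with a median of 3.15, as for Ccl3 (25.4-fold, 21.5 to 30.1), Tnf (16.8-fold, 12.7 to 22.5) and Cxcl2 (3.07-fold, 3.01 to 3.13). With a minimum of 1 UMI the CPM median of neutrophil chemoattractants and growth factors was 1.80 in place of 2.91. Of 9 monocyte and lymphocyte chemoattractants 7 were higher and 1 lower (median 2.47), with Cxcl9 at 20.3-fold (11.2 to 41) and Ccl6 at 2.03-fold lower. Of 11 glycolysis and hypoxia genes 9 were higher (median 2.34), such as Hk2 (7.69-fold, 5.78 to 10.4) and Ldha (4.47-fold, 3.93 to 5.11). The IL-1 family and inflammasome list had 5 of 15 members higher and 2 lower (median 0.92, percentile 99.8). Il1rn, the gene of the receptor antagonist, was 16.1-fold (13.9 to 18.7) higher and the decoy receptor gene Il1r2 was 2.89-fold (2.78 to 3) lower.

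The granule and antimicrobial list went both ways in day 2 neutrophils, with 3 of 14 genes higher and 5 lower (median −0.31, percentile 5.5). Chil3 was 6.37-fold (5.08 to 8.05) lower and Ncf1 2.21-fold higher. Within clusters 3 and 11 the granule median was 1.16 and 0.08, that of interferon response 2.37 and 2.3, of neutrophil chemoattractants 1.94 and 0.7 and of glycolysis 2.2 and 0.55. Dectin and CARD9 signalling had 2 of 16 higher and 2 lower (median 0.44). Clec4n, the gene of Dectin-2, was 21.3-fold (16.1 to 28.7) higher and the kinase gene Syk 2.13-fold (2 to 2.26) lower. Chromatin repressors and histone demethylase had 2 of 10 higher and 1 lower (median 0.29), with Suz12 2.41-fold (1.82 to 3.25) higher and Ezh2 2.31-fold (1.17 to 4.64) lower. In the C1q list 1 of 8 genes, C1qa, was lower (2.27-fold, 1.94 to 2.66; list median −0.07). None of 13 oxidative phosphorylation genes reached 2-fold, as with Atp5b, 1.48-fold higher, and the list median of 0.02 was −0.22 on CPM. The immediate early and heat shock list had 1 of 12 higher, Jun (2.52-fold, 2.29 to 2.78), and 1 lower, Fosb (6.79-fold, 5.96 to 7.76), and its median of 0.11 was −0.14 on CPM. Cell cycle genes were lower for 3 of 4, among them Mki67 (3.82-fold, 2.26 to 6.66), with a median of −1.77. Proximal tubule transcripts, read as background RNA, were lower for 5 of 6, such as Miox (20.4-fold, 8.24 to 65.2), with a median of −2.71.

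On day 6, neutrophils again held more chemokine transcripts than in naive kidney and fewer of Camp, Ngp and Ltf. Highest were Il1a (141-fold, 68.6 to 352), Cxcl3 (51.1-fold, 40.6 to 65.2), Cxcl10 (33.0-fold, 19.3 to 62), Ccl3 (28.2-fold, 24 to 33.4) and Spp1, the gene of osteopontin (26.0-fold, 19.4 to 35.5). The 40 tubule cells of day 6 were too few to enter the minimum share against free RNA. On day 2 Spp1 was 338 CPM in neutrophils and 20655 in tubule cells, so free RNA was not excluded for it. Lowest were Camp (32.8-fold lower, 29.8 to 36.3), Ngp (27.5-fold, 25.4 to 29.7), Ltf (11.8-fold, 10.4 to 13.4), Acpp (5.95-fold, 4.97 to 7.12) and Chil3 (5.27-fold, 4.56 to 6.08). The log2 ratio of Cxcl10 was 2.33 in place of 5.04 with separate clustering. All 8 measured neutrophil chemoattractants and growth factors were at least 2-fold higher (median 2.62, percentile 100), as were 7 of 10 monocyte and lymphocyte chemoattractants (median 2.77). An example was Ccl4 (14.4-fold, 13.1 to 16). Of the latter list, Ccl2, Ccl7, Ccl8, Ccl9 and Ccl12 stood below 0.2 of their CPM in mononuclear phagocytes. Interferon response genes were higher for 10 of 14 (median 1.5), such as Gbp2 (7.55-fold, 5.99 to 9.66) and Isg15 (3.55-fold, 3.2 to 3.95). Glycolysis and hypoxia genes were higher for 5 of 11 (median 0.99), such as Hk2 (4.16-fold, 3.14 to 5.61).

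Of the IL-1 family list 4 of 16 genes were higher in day 6 neutrophils (median 0.77), among them Il1rn (8.39-fold, 7.28 to 9.73). The granule list had 6 of 14 lower and 1 higher (median −0.71, percentile 0), with Lyz2 2.38-fold (2.29 to 2.47) lower and Nos2 15.3-fold (4.17 to 127, from 2 naive UMIs) higher. Within clusters 3 and 11 the granule median was 0.93 and 0.04 on day 6, that of neutrophil chemoattractants 2.91 and 1.25, of interferon response 1.39 and 1.89 and of glycolysis 1.46 and 0.17. Cell cycle genes were lower for 4 of 9 (median −0.78), such as Ube2c (5.44-fold, 3.66 to 8.04). Tubule transcripts were lower for 7 of 7 (median −4.46). The stress list of immediate early and heat shock genes had 3 of 12 higher and 1 lower (median 0.27), with Hspa1a 2.96-fold (2.51 to 3.5) higher. In the Dectin list 1 of 16 was higher, Clec4n at 17.9-fold (median 0.30). The chromatin list had 1 of 12 higher, Suz12 at 2.59-fold (1.99 to 3.41; median 0.23). No member of the C1q list (8 genes, median −0.19) or of oxidative phosphorylation (13 genes, median −0.22) reached 2-fold.

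From day 2 to day 6, the glycolysis and interferon response lists had negative median log2 ratios in neutrophils. Lowest on day 6 were Gstm1, a glutathione transferase (15.3-fold lower, 12 to 19.7), Ly6i (8.53-fold, 7.85 to 9.27), Blvrb (8.25-fold, 7.28 to 9.35), the peroxiredoxin gene Prdx1 (5.81-fold, 5.47 to 6.18) and Srxn1, whose product reactivates peroxiredoxins (5.6-fold, 4.83 to 6.51). Highest were Cntn5 (9.06-fold), Dach1 (6.9-fold, 5.83 to 8.21), Cxcl3 (6.8-fold, 6.38 to 7.25), Lars2 (5.18-fold, 4.37 to 6.17) and Cpeb2 (4.46-fold, 4.07 to 4.89). Of 11 glycolysis and hypoxia genes 5 were at least 2-fold lower (median −0.97, percentile 0), such as Pgk1 (3.4-fold, 3.19 to 3.61). Of 14 interferon response genes 5 were lower (median −0.63), such as Gbp5 (3.36-fold, 3.04 to 3.71). The mix of clusters differed between the days, with cluster 9 at 615 of 1159 day 2 and 873 of 4050 day 6 cells. Within 3 clusters the medians were −2.5 to −0.51 for interferon response and −0.79 to −0.35 for glycolysis. The monocyte and lymphocyte chemoattractants went both ways (median −0.28), with Cxcl10 4.52-fold (4.3 to 4.76) lower and Ccl6 2.57-fold (2.46 to 2.69) higher among 4 lower and 3 higher of 10. Among them Ccl2 and Ccl8, which were higher, and Ccl5, which was lower, stood below 0.2 of their CPM in another class. Of 8 neutrophil chemoattractants and growth factors 2 were higher and 1, Tnf, was 2.5-fold (2.35 to 2.67) lower (median 0.55, percentile 94.8). Cell cycle genes had a median of 0.98 (percentile 98.9) with 1 of 9 past 2-fold, Ccnb2 (3.29-fold, 1.2 to 12.6, from 4 day 2 UMIs). Within 2 single clusters the cell cycle median was only 0.2 to 0.34. Stress genes were higher for 3 of 12 (median 0.41), such as Fosb (3.18-fold, 2.82 to 3.6), and granule genes lower for 3 of 14 (median −0.25), such as Cybb (3.39-fold, 3.14 to 3.65). In the IL-1 family list 3 of 16 were higher and 2 lower (median 0.23), with Il1rap 3.32-fold (3.11 to 3.54) higher and Il18bp 4.59-fold (3.94 to 5.35) lower.

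As a class made of different clusters, mononuclear phagocytes of day 2 held more glycolysis, tissue-repair and chemoattractant transcripts and fewer MHC class II transcripts than those of naive kidney, and most of the list medians were smaller within single clusters. Highest were Slc7a2, a cationic amino acid transporter (798-fold, 342 to 2458), Arg1, the gene of arginase 1 (313-fold, 225 to 449), Saa3 (283-fold, 238 to 340), complement factor B, Cfb (88.3-fold, 76.1 to 103), and AA467197 (55.9-fold, 50.8 to 61.8). Lowest were Dlc1 (62.0-fold lower, 57.1 to 67.4), Agmo, an alkylglycerol monooxygenase (56.8-fold, 51 to 63.4), Abtb3 (41.2-fold, 36 to 47.3), Plxna4, a semaphorin receptor subunit (40.5-fold, 37.3 to 44.1), and Hs3st3a1 (39.4-fold, 34.1 to 45.7). Different clusters held the class in each library. Cluster 0 held 4434 of 6180 naive cells, clusters 1 and 4 held 2319 and 1941 of 7609 day 2 cells, and cluster 2 held 2159 of 5636 day 6 cells. A cluster mostly of 1 library may be that library and not a cell type. Dlc1, Plxna4, Agmo and Hs3st3a1 were also among the leading genes of cluster 0, Cfb and Ly6i of cluster 1, Ccl7, Ccl8 and C1qa of cluster 2, and Slc7a2, Arg1, Nos2, Gpnmb, Fn1 and AA467197 of cluster 4. C1qa, C1qb, C1qc, Mrc1, Chil3 and Plac8 were markers used for naming.

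With separate clustering the log2 ratios on day 2 were −9.96 for Dlc1 (−5.95 with joint clustering), −8.31 for Plxna4 (−5.34), −7.65 for Hs3st3a1 (−5.30), −6.34 for Abtb3 (−5.36) and −6.45 for Agmo (−5.83). At resolution 2 the value of AA467197 was 7.0 in place of 5.81.

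All 11 glycolysis and hypoxia genes were at least 2-fold higher in day 2 mononuclear phagocytes, with a median log2 ratio of 3.19 at percentile 100. Among them were Pgk1 (11.1-fold, 10.6 to 11.6), Ldha (7.66-fold, 7.4 to 7.93) and the glucose transporter Slc2a1 (7.15-fold, 6.65 to 7.69). Tissue-repair macrophage genes were higher for 10 of 13 and lower for 1 (median 3.02). Gpnmb was 371-fold (188 to 860) and Spp1 25.8-fold (24.2 to 27.6) higher, and the mannose receptor gene Mrc1 was 8.5-fold (8.17 to 8.85) lower. Of 9 MHC class II presentation genes 6 were lower (median −1.68, percentile 0). These included H2-Eb1 (5.68-fold, 5.65 to 5.72), Cd74 (4.36-fold, 4.35 to 4.38) and Ciita, the class II transactivator (5.64-fold, 5.44 to 5.85). In the Dectin and CARD9 list 5 of 16 were higher and 1 lower (median 0.75, percentile 91.7). Higher were the lectin receptor genes Clec4d (24.4-fold, 22.2 to 27), Clec4n (18.7-fold, 17.3 to 20.2) and Clec4e (13.9-fold, 13.1 to 14.9) and the signalling protease Malt1 (3.86-fold, 3.75 to 3.98). The granule and antimicrobial list had 9 of 16 higher and 2 lower (median 1.42), with Nos2 600-fold (234 to 2203) and Lcn2 12.7-fold (11.1 to 14.7) higher.

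Neutrophil chemoattractants and growth factors were higher for 5 of 9 and lower for 2 (median 1.80) in day 2 mononuclear phagocytes, with Cxcl3 291-fold (153 to 636) and Il6 16.6-fold (11.5 to 24.9) higher. Of 10 monocyte and lymphocyte chemoattractants 6 were higher (median 1.85), such as Ccl7 (17-fold, 15.1 to 19.3) and Ccl5 (6.54-fold, 6.32 to 6.76). Oxidative phosphorylation genes were higher for 6 of 13 (median 1.22), such as Cox5a (3.53-fold, 3.43 to 3.63). The IL-1 family list had 6 of 16 higher and 1 lower, and its median of 0.20 was −0.16 on CPM. Il1rn was 63.3-fold (51.6 to 78.6) and Il1a 10.6-fold (9.28 to 12.1) higher, and Aim2 2.52-fold (2.43 to 2.62) lower. Interferon response genes went both ways (2 of 14 higher, 2 lower, median 0.48), with Gbp2 4.08-fold (3.82 to 4.36) higher and Ifit2 5.44-fold (5.17 to 5.71) lower. In the C1q list 1 of 8 was higher, Lrp1 (4.05-fold, 3.88 to 4.23), and 3 were lower, among them C1qa (3.68-fold, 3.65 to 3.71). Its median of 0.26 was −0.09 on CPM. Within 6 single clusters the C1q median was −0.49 to 0.95, above 0 in 4 and below in 2. The chromatin list had 2 of 12 lower, Dnmt3a (2.1-fold, 2.04 to 2.17) and Sirt1 (2.32-fold, 2.15 to 2.51), with a median of 0.17 that was −0.18 on CPM. Stress genes were lower for 7 of 12 (median −1.22, percentile 0), such as Hspa1b (21.0-fold, 20.5 to 21.6) and Jun (4.8-fold, 4.73 to 4.88). Tubule transcripts were lower for 8 of 8 (median −3.86), such as Lrp2 (37.9-fold, 25 to 60.4). Of 10 cell cycle genes 1 was lower, Mki67 (2.64-fold, 2.51 to 2.79; median −0.28). Within 5 single clusters the cell cycle median was −0.39 to 2.13, above 0 in 3 and below in 2.

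Within the 6 mononuclear phagocyte clusters with at least 50 cells in both libraries, the list medians on day 2 were 1.09 to 2.08 for glycolysis and hypoxia and 0.86 to 1.91 for tissue repair in 5 clusters and −0.05 in cluster 20. They were −0.51 to −0.13 for MHC class II in 5 clusters and −1.41 in cluster 5, −0.17 to 0.37 for neutrophil chemoattractants, 0.03 to 2.2 for monocyte and lymphocyte chemoattractants and −1.38 to 0.98 for interferon response. Cluster 5 was of low UMI count (median 1030), with Cntn5 first among its leading genes. It also gave the highest tissue-repair medians, 1.91 on day 2 and 3.09 on day 6, against 1.5 and 2.2 in cluster 17. Within 7 clusters on day 6 they were −0.1 to 3.09 for tissue repair, 0.23 to 1.15 for glycolysis, −0.65 to −0.12 for MHC class II, −0.14 to 0.92 for neutrophil chemoattractants, 0.22 to 2.05 for monocyte and lymphocyte chemoattractants and −1.0 to 1.33 for interferon response. On day 6 over day 2, within 8 clusters, they were 0.06 to 1.11 for MHC class II, −0.66 to 1.33 for cell cycle, −0.04 to 0.71 for interferon response, −1.03 to −0.36 for glycolysis and −0.74 to 0.13 for granule genes.

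**Figure D3:**
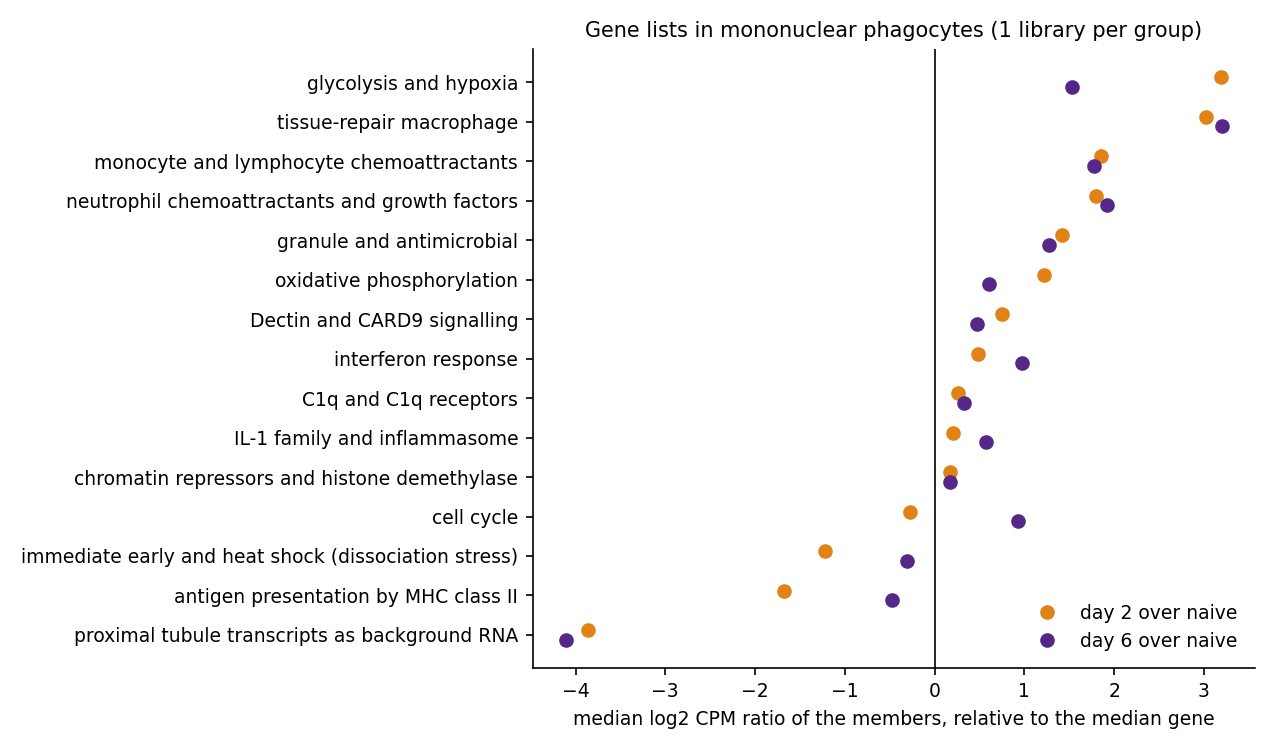
Median log2 ratio of CPM relative to the median gene (horizontal axis) of 15 gene lists in mononuclear phagocytes, for day 2 over naive (orange) and day 6 over naive (purple); each point is the median of the list's measured genes, with 1 library per group and no interval. Glycolysis and hypoxia genes stood at 3.19 on day 2 and 1.53 on day 6, and MHC class II genes at −1.68 and −0.48.

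As a class, mononuclear phagocytes of day 6 held more chemokine and repair transcripts than those of naive kidney. Highest were the eotaxin family gene Ccl24 (452-fold, 290 to 752), Arg1 (429-fold, 309 to 617), Saa3 (56.3-fold, 47.2 to 67.7) and the monocyte chemoattractants Ccl8 (52.9-fold, 45.8 to 61.4) and Ccl7 (41.2-fold, 36.5 to 46.7). Lowest were Abtb3 (12.1-fold lower, 11 to 13.2), the heat shock genes Hspa1b (8.85-fold, 8.67 to 9.04) and Hsph1 (8.83-fold, 8.44 to 9.24), Hs3st3a1 (8.43-fold, 7.75 to 9.18) and Dlc1 (8.36-fold, 8.05 to 8.69). With separate clustering the log2 ratios were −5.82 for Dlc1 (−3.06 with joint clustering), −4.86 for Abtb3 (−3.59), −5.34 for Hs3st3a1 (−3.08) and −3.76 for Hspa1b (−3.15). The value of Saa3 was 5.05 in place of 5.82 in macrophage clusters alone, and that of Ccl8 6.37 in place of 5.72 with at least 500 genes per cell.

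Tissue-repair genes were at least 2-fold higher for 10 of 13 in day 6 mononuclear phagocytes (median 3.20, percentile 100), such as Gpnmb (219-fold, 111 to 508) and Retnla (28.1-fold, 21.8 to 36.9). The CPM median of this tissue-repair macrophage list was 4.42 in macrophage clusters alone, in place of 3.04. Monocyte and lymphocyte chemoattractants were higher for 9 of 11 (median 1.77), among them Cxcl13 (at least 64.6-fold, with 0 naive UMIs) and Ccl2 (5.15-fold, 4.93 to 5.38). Neutrophil chemoattractants were higher for 5 of 9 (median 1.92), with Cxcl3 681-fold (359 to 1490) higher. Glycolysis and hypoxia genes were higher for 10 of 11 (median 1.53), such as Slc2a1 (3.64-fold, 3.37 to 3.93), and oxidative phosphorylation genes for 2 of 13 (median 0.61), such as Cox5a (3.02-fold, 2.93 to 3.11). The granule list had 8 of 15 higher and 2 lower (median 1.27), as Slpi was 4.73-fold higher. The interferon list had 6 of 14 higher (median 0.97), such as Gbp2 (3.65-fold, 3.41 to 3.92) and Isg15 (2.4-fold, 2.3 to 2.51). Dectin and CARD9 genes were higher for 6 of 16 (median 0.47), with Clec4n at 15.8-fold (14.6 to 17.1). IL-1 family genes were higher for 4 of 16 (median 0.57), with Il1rn at 37.1-fold (30.1 to 46.1).

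In the C1q list 1 of 8 was higher, Lrp1 (2.24-fold, 2.14 to 2.34; median 0.33). In the chromatin list none of 12 reached 2-fold (median 0.17), with the histone demethylase gene Kdm6b 1.36-fold higher and Sirt1 1.84-fold lower. MHC class II genes had a median of −0.48 (percentile 0.2) on day 6, with Cd74 1.69-fold (1.69 to 1.7) and H2-Ab1 1.72-fold (1.72 to 1.73) lower, and 1 of 9, Cd40, 2.08-fold (1.92 to 2.25) higher. Cell cycle genes were higher for 2 of 10 (median 0.93), Rrm2 (2.54-fold, 2.23 to 2.9) and Birc5 (2.18-fold, 2.02 to 2.35). Stress genes were lower for 4 of 12 (median −0.31), such as Hspa1a (6.27-fold, 6.15 to 6.4). Tubule transcripts were lower for 8 of 8 (median −4.11).

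In mononuclear phagocytes on day 6 over day 2, the MHC class II, cell cycle and interferon response lists had positive median log2 ratios, and the glycolysis and granule lists negative ones. Highest on day 6 were Ccl24 (31.3-fold, 28.6 to 34.2), Mrc1 (11.2-fold, 10.8 to 11.6), Clec4b1 (10.4-fold, 9.66 to 11.3), Cntn5 (8.57-fold, 8.4 to 8.75) and the lectin gene Mgl2 (8.33-fold, 7.93 to 8.75). Lowest were Tppp3 (6.85-fold lower, 6.41 to 7.34), Ly6i (6.36-fold, 6.11 to 6.61), the argininosuccinate synthase gene Ass1 (5.21-fold, 5.02 to 5.4), Saa3 (5.03-fold, 4.93 to 5.14) and haptoglobin, Hp (3.73-fold, 3.65 to 3.83). In macrophage clusters alone the log2 ratios were −3.34 for Saa3 (−2.33 with monocytes) and −3.24 for Hp (−1.90), and with separate clustering that of Mgl2 was 4.72 in place of 3.06.

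MHC class II genes were at least 2-fold higher on day 6 than on day 2 for 5 of 9 (median 1.08, percentile 100), such as H2-Eb1 (3.6-fold, 3.58 to 3.62). So were cell cycle genes for 8 of 10 (median 1.13), such as Birc5 (3.46-fold, 3.23 to 3.72), and interferon response genes for 5 of 14 (median 0.61), such as Ifit2 (4.51-fold, 4.3 to 4.74). Glycolysis and hypoxia genes were lower for 8 of 11 (median −1.74, percentile 0), such as Gapdh (3.43-fold, 3.39 to 3.46). Granule genes were lower for 6 of 15 (median −0.75), such as Nos2 (3.84-fold, 3.57 to 4.14). Of these, Lcn2, Ltf, Camp and Slpi stood below 0.2 of their CPM in neutrophils on day 2. Of the 13 repair genes 2 were higher, among them Retnla (37.0-fold, 29.9 to 46.3), with a median of −0.37. Within 8 single clusters the repair median was −0.58 to 0.62, above 0 in 6 and below in 2. The CPM median of this tissue-repair macrophage list was 0.55 with separate clustering, in place of −0.20. The C1q list had 3 of 8 higher, among them C1qa (3.45-fold, 3.42 to 3.48; median 0.04). In the Dectin list 2 of 16 were lower, Clec4d (2.56-fold) and Clec4e (2.39-fold), with a median of −0.15 that was 0.02 on CPM. Stress genes were higher for 5 of 12 (median 0.63), such as Egr1 (2.77-fold, 2.68 to 2.87). Of 11 monocyte and lymphocyte chemoattractants 4 were higher and 1 lower (median 0.46, percentile 99.4), and of 9 neutrophil chemoattractants 2 were higher (median 0.33).

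In T cells of day 2 the interferon response and glycolysis lists had positive median log2 ratios over naive kidney, although few of their genes reached 2-fold, and the stress list had a negative one. Highest were Plac8 (9.07-fold, 8.38 to 9.83), Pmepa1 (4.54-fold, 3.98 to 5.21), Ly6a, the gene of Sca-1 (3.57-fold, 3.38 to 3.77), granzyme K, Gzmk (3.49-fold, 3.12 to 3.91), and Serpina3g (3.42-fold, 2.98 to 3.95). Lowest were Cntn5 (11.9-fold lower, 11.5 to 12.3), Fosb (6.51-fold, 6.07 to 6.98), Nav2 (5.54-fold, 4.89 to 6.29), Hspa1a (5.21-fold, 4.79 to 5.66) and Hspa1b (5.07-fold, 4.75 to 5.4). With separate clustering the log2 ratios were 4.84 for Gzmk (1.80 with joint clustering) and 3.0 for Serpina3g (1.78). With the unnamed T-marker clusters counted that of Gzmk was 2.44 and that of Nav2 −1.85 in place of −2.47. Clusters 6, 7, 15 and 18 held 335, 217, 213 and 55 naive, 874, 814, 311 and 168 day 2 and 1101, 1060, 367 and 484 day 6 T cells. Gzmk, Gzmb, Ccl5 and Nkg7 were also among the leading genes of cluster 7. Within these 4 clusters the median on day 2 was 0.09 to 1.17 for interferon response, 0.75 to 1.3 for glycolysis and −1.07 to −0.38 for stress genes.

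Of the cytotoxic effector list 4 of 10 genes were at least 2-fold higher in day 2 T cells (median 0.43, percentile 86.5), among them Gzmb (2.6-fold, 2.4 to 2.83), Nkg7 (2.49-fold, 2.4 to 2.58) and Ccl5 (2.3-fold, 2.26 to 2.33). The interferon list had a median of 0.89 (percentile 100) with 1 of 14 past 2-fold, Oasl1 (2.38-fold, 1.45 to 4.07). Ifit2 was 1.95-fold (1.62 to 2.35) lower, and the intervals of Mx1, Gbp5 and Irgm1 included 1. Glycolysis and hypoxia genes had 2 of 11 higher (median 0.96), with Gapdh at 2.67-fold (2.57 to 2.77). None of 13 oxidative phosphorylation genes passed 2-fold, with a median of 0.76, as Cox5a was 1.54-fold higher.

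Naive and central memory T genes were lower for 3 of 8 in day 2 T cells (median −0.60, percentile 0.4), such as Ccr7 (3.37-fold, 2.69 to 4.24) and Klf2 (2.06-fold, 1.96 to 2.16). The class leaves out the unnamed cluster 16, whose leading genes included Lef1, Satb1, Tcf7 and Ccr7 of this list. The CPM median of the naive and central memory T list, −0.88, was −1.5 with the T-marker clusters counted and −1.65 with separate clustering. Of the lymphocyte activation and checkpoint list 1 of 11 was lower, Il2ra (2.64-fold, 2.24 to 3.11), with a median of 0. With separate clustering its CPM median was 0.52 in place of −0.27, and that of the cytotoxic effector list 2.03 in place of 0.15. No cell cycle gene of 10 reached 2-fold (median 0.43), and that list's CPM median of 0.16 was 0.79 with the T-marker clusters counted. Stress genes were lower for 6 of 12 (median −0.70, percentile 0) and tubule transcripts for 8 of 8 (median −3.14).

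On day 6, the cell cycle and interferon response lists in T cells had positive median log2 ratios over naive kidney. Highest were Plac8 (8.0-fold, 7.4 to 8.66), the interferon-inducible gene Ifi27l2a (3.32-fold, 3.2 to 3.43), Gzmb (3.22-fold, 2.98 to 3.49), Ly6a (3.22-fold, 3.05 to 3.4) and Ly6c2 (3.0-fold, 2.85 to 3.17). Lowest were Hspa1a (8.41-fold lower, 7.79 to 9.09), Hspa1b (8.38-fold, 7.89 to 8.89), Rgcc (4.44-fold, 4.16 to 4.75), Zbtb16, the gene of the transcription factor PLZF of innate-like T cells (3.6-fold, 3.22 to 4.01), and Hsph1 (3.44-fold, 3.21 to 3.68). With separate clustering the log2 ratios were 3.72 for Gzmb (1.69 with joint clustering) and 2.32 for Ly6c2 (1.59). Cell cycle genes were at least 2-fold higher for 5 of 10 (median 1.13, percentile 100), such as Birc5 (2.51-fold, 2.25 to 2.8) and Rrm2 (2.53-fold, 2.2 to 2.91). The CPM median of the cell cycle list, 1.04, was 2.0 with separate clustering and 1.79 with the T-marker clusters counted. Interferon response genes were higher for 4 of 14 (median 0.80), such as Isg15 (2.51-fold, 2.2 to 2.87) and Ifit3 (2.5-fold, 2.09 to 3.02). Within clusters 6, 7, 15 and 18 the medians were 0.04 to 2.02 for cell cycle and 0.14 to 1.2 for interferon response.

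Of the naive and central memory T list 2 of 8 were lower in day 6 T cells, Ccr7 (4.26-fold, 3.5 to 5.2) and Klf2 (2.64-fold, 2.53 to 2.75), with a median of −0.50. Its CPM median of −0.60 was −1.96 with separate clustering and −1.54 with the T-marker clusters counted. The cytotoxic effector list had 1 of 10 higher, Gzmb (median 0.11), with a CPM median of 1.89 in place of 0.02 with separate clustering. None of 11 genes of the lymphocyte activation and checkpoint list reached 2-fold (median 0.29), and its CPM median was 0.99 in place of 0.20 with separate clustering. No glycolysis (11 genes, median 0.53) or oxidative phosphorylation gene (13 genes, median 0.52) reached 2-fold. Stress genes were lower for 6 of 12 (median −0.96) and proximal tubule transcripts as background RNA for 8 of 8 (median −5.15), with a CPM median of −4.22 in place of −5.24 at a minimum of 100 UMIs.

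From day 2 to day 6 the T cell cycle list was at least 2-fold higher for 5 of 10 genes (median 0.79, percentile 100), such as Mki67 (2.44-fold, 2.3 to 2.59) and Cdk1 (2.38-fold, 2.12 to 2.69). Within the 4 T clusters its median was 0.1 to 0.47. Highest were Cntn5 (4.35-fold, 4.2 to 4.49), the histone genes H1f5 (3.0-fold, 2.8 to 3.22) and H2ac8 (2.54-fold, 2.3 to 2.81), which were among the leading genes of cluster 18, Inpp4b (2.67-fold, 2.6 to 2.75) and Fhit (2.61-fold, 2.37 to 2.87). Lowest were Serpina3g (2.64-fold lower, 2.44 to 2.85), Nop53 (2.47-fold, 2.36 to 2.59), B2m, the light chain of MHC class I (2.42-fold, 2.38 to 2.45), Pmepa1 (2.35-fold, 2.2 to 2.5) and Sod1, superoxide dismutase 1 (2.31-fold, 2.17 to 2.46). Of the cytotoxic list 2 of 10 were lower (median −0.19), Gzmk (2.04-fold, 1.93 to 2.16) and Ccl5 (2.2-fold, 2.18 to 2.22). In the activation list 1 of 11 was higher, Il2ra (3.08-fold, 2.7 to 3.53). Glycolysis genes had 1 of 11 lower (median −0.53, percentile 0.1), and tubule transcripts 3 of 4 (median −2.52).

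In NK cells, 3 of 10 cytotoxic effector genes were at least 2-fold higher on day 2 than in naive kidney (median 0.50, percentile 80.5), Gzmk (17.4-fold, 5.68 to 86.9, from 3 naive UMIs), Ccl5 (2.53-fold, 2.47 to 2.58) and Klrg1 (2.14-fold, 1.76 to 2.63). On day 6 none of 9 reached 2-fold (median −0.08), with Gzmb 1.59-fold (1.4 to 1.81) lower than in naive cells. In tubule cells, of which the bead selection left 595 naive and 97 day 2 cells, 6 of 8 tubular injury genes were higher on day 2 (median 2.73, percentile 100). Among them were complement C3 (117-fold, 73.2 to 198), Havcr1, the gene of kidney injury molecule 1 (59.9-fold, 23 to 198), Spp1 (40.7-fold, 39 to 42.4) and Lcn2 (8.83-fold, 7.06 to 11). Krt18, at 1.07-fold (0.683 to 1.6), had an interval that included 1. The class came from different clusters in each library. Clusters 22, 25 and 29 held 275, 199 and 121 naive and 19, 56 and 22 day 2 cells. Spp1 was higher in each of them, from 10.6-fold in cluster 29 to 102-fold in cluster 22, as was C3. The Lcn2 interval lay above 1 in cluster 29 alone, and the Havcr1 interval in cluster 22 alone. In mononuclear phagocytes of the day 2 library Spp1 was 637 CPM against 20655 in tubule cells, Lcn2 68.7 against 283 and C3 180 against 410. Neutrophils there held 2301 CPM of Lcn2 and 261 of C3. Cd44 was higher in both (493 and 1354 CPM) than in tubule cells (152), and Havcr1 was higher in plasmacytoid dendritic cells (90.5 against 55.1). RNA of immune cells was not subtracted. The day 6 library held 40 tubule cells and was not compared.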

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

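Of the tests in this part, the one on the mix of mononuclear phagocyte clusters for the stress genes was set before its result was seen, and the others were chosen only after the result was seen. Some results stood out because day 2 and day 6 lay on opposite sides of naive kidney, and these differences between the days were not tested. The NK share was 0.763 points above naive on day 2 and −0.869 points from it on day 6. Unnamed cluster 13, with T markers but the NK marker Klre1 among its leading genes, went the other way on both days. It held 3.42%, 1.51% and 3.86% of naive, day 2 and day 6 cells, and counted as NK it would put day 2 below naive. For mononuclear phagocytes the differences from naive were 8.43 and −13.5 points. However, both lay below naive with separate clustering (−18.9 and −27.6), and the one on day 6 was −0.057 at resolution 2. Among named immune cells alone their day 2 share, 62.4% (61.5 to 63.2), was near that of naive kidney, 61.0% (60 to 61.9). Clec7a in neutrophils stood at 0.647 of naive on day 2 and at 1.09 on day 6. Outside the compared classes, unnamed cluster 32, which carried neutrophil markers but led with monocyte genes such as Ace, Cd300e and Treml4, held 0.0503% of naive, 0.15% of day 2 and 0.244% of day 6 cells, at a median of 10252 UMIs.

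Cntn5 was lower on day 2 than in naive kidney in neutrophils, mononuclear phagocytes and T cells. A library-wide difference that is the same in every cell type was tested over 10 classes: 0 of them lay more than 1 (log2) from the median class of −3.98. The ratios were not equal within this limit. They went from −4.93 (−4.96 to −4.9) in mononuclear phagocytes to −3.15 (−3.44 to −2.88) in plasmacytoid dendritic cells. Free RNA shared by all droplets of a library predicts a like number of UMIs per cell, within 3 times, in every class, and the highest over the lowest class of naive kidney was 1.27, at 26.9 to 34.2 Cntn5 UMIs per cell. Among 76 genes with at least 2 UMIs per cell in every class, Cntn5 was the only 1 with a spread between classes under 1.5. Their median spread was 12.2. Free RNA may therefore be a source of the Cntn5 UMIs, while a response to infection stays open with 1 library per group.

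On day 2 the immediate early and heat shock list had a negative median in mononuclear phagocytes and T cells, with 7 and 6 of 12 genes at least 2-fold lower, whereas Hspa8 was 1.74-fold and 1.56-fold higher. A different mix of mononuclear phagocyte clusters was argued against as the whole cause, since the list's median, relative to the median gene, lay below −0.5 in 6 of 6 clusters, from −1.26 to −0.88. Cluster 0, with 4434 of 6180 naive cells, could not be compared in this way. Neither could clusters 1 and 4, with 2319 and 1941 of 7609 day 2 cells. A harsher preparation of the naive library acting on every cell type predicts a median below −0.5 in every class. In the data 7 of 10 classes lay below −0.5 and 1, the neutrophils at 0.11, lay above 0. Preparation and infection cannot be told apart here, because each group had 1 library.

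Il1b and C1qbp were both higher in mononuclear phagocytes on day 2. Within the 6 clusters with at least 50 cells in both libraries, the interval of the ratio lay above 1 in 4 for C1qbp and in 5 for Il1b, which argues against a different mix of clusters as the whole cause. Cluster 5, of low UMI count (median 1030), was among the 5 for Il1b but not among the 4 for C1qbp. Clusters 1 and 4, which held most day 2 cells, had 30 and 0 naive cells and could not be compared in this way. Neither could cluster 0, which held 4434 of 6180 naive cells and 31 day 2 cells. Il1b stood at 1589 CPM in day 2 cells of cluster 4 and at 502 CPM in naive cells of cluster 0. The mix of clusters was thus not excluded as a part of the class ratio. Free RNA of neutrophils would give a like number of Il1b UMIs per cell in other classes. On day 2 this was 9.78 in mononuclear phagocytes, 1.48 in B cells and 0.471 in T cells, and by CPM, in which the test was set, mononuclear phagocytes held 2.33 times the B cell level. This argues against free RNA as the whole source. A response to infection is a candidate explanation that 1 library per group could not test.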

How the results depend on the processing

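The alternatives that left out low-UMI clusters, counted unnamed clusters with T or mononuclear phagocyte markers, or used macrophage clusters alone were chosen after seeing the data. The cause of the shifts below was not tested. Of class share differences, 112 values under alternatives were within the interval, 46 moved beyond it and 2 reversed; for Il1b, C1qbp and Clec7a these counts were 188, 58 and 4. List medians were within it in 961 values and beyond it in 214. A list median counted as reversed only if it lay outside the middle 95% of random lists, and none of those reported changed sign; of the other lists, 22 values changed sign, 15 of them beyond the interval. With separate clustering, these included the lymphocyte activation and checkpoint list in T cells on day 2, at 0.52 from −0.27, and the tissue-repair macrophage list from day 2 to day 6, at 0.55 from −0.2. No NK cluster was named in the naive and day 6 libraries and no tubule cluster in day 6 with separate clustering, so those share differences have no value there. Named genes kept their direction in 623 values within the interval and 157 beyond it. The numbers of lists outside the middle 95% of random lists stayed within 1.5 times in all 96 values. Thinned to 500 UMIs, which counts fewer UMIs per cell, 31 shares of cells with a UMI moved and 5 stayed within the interval. No paired analysis was possible because no test across samples was run (1 library per group).

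Share differences are in points for day 2 minus naive, day 6 minus naive and day 6 minus day 2, and gene values are log2 ratios in that order. They were 5.41, 23.7 and 18.3 for neutrophils, 8.43, −13.5 and −21.9 for mononuclear phagocytes and 10.3, 13.6 and 3.31 for T cells. Il1b stood at 0.3, 0.5 and 0.2 in neutrophils and 1.13, 0.84 and −0.29 in mononuclear phagocytes, and C1qbp at 0.93, 0.76 and −0.17 in mononuclear phagocytes.

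With separate clustering, neutrophils were at 22.7 on day 6 and 17.2 from day 2 to day 6, mononuclear phagocytes at −18.9 (reversed), −27.6 and −8.76, and T cells at 6.92, 2.01 and −4.91 (reversed). Il1b was then 0.55 and 0.24 in neutrophils on day 6 over naive and over day 2, and 1.16, 1.02 and −0.14 in mononuclear phagocytes, with C1qbp at −0.11 for day 6 over day 2. Counting the unnamed clusters with macrophage or monocyte markers there gave 6.91 and −15.6. At resolution 2, neutrophils were at 17.3 from day 2 to day 6, mononuclear phagocytes at 16.7, −0.057 and −16.7, and T cells at 9.31, 15.4 and 6.07, with Il1b at 1.18 and 0.91 and C1qbp at 1.05 and 0.86 in mononuclear phagocytes on day 2 and day 6 over naive. At resolution 0.5, mononuclear phagocytes were at 4.94 on day 2 and −17.5 from day 2 to day 6, and T cells at 9.31, 15.3 and 6.04.

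With at least 500 genes, neutrophils were at 22.7 on day 6 and 17.3 from day 2 to day 6, mononuclear phagocytes at 3.46 and −16.4 on day 2 and from day 2 to day 6, and Il1b in them at 1.19 and 0.9 over naive. With at most 10% mitochondrial UMIs, neutrophils were at 24.9 and 19.5 for day 6, mononuclear phagocytes at 6.12 and −16.4 over naive, and T cells at 15.2 and 5.44 for day 6. With doublets kept, mononuclear phagocytes were at 4.74 on day 2 and −17.4 from day 2 to day 6, Il1b at 0.22, 0.45 and 0.23 in neutrophils and −0.31 for day 6 over day 2 in mononuclear phagocytes, and Clec7a in T cells at −0.03 for day 6 over day 2, reversed from 0.28. Without low-UMI clusters, neutrophils were at 6.4 on day 2, mononuclear phagocytes at 7.12 on day 2 and −20.4 from day 2 to day 6, T cells at 11.5 and 14.5 over naive, and Il1b in neutrophils at 0.47 on day 6.

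With the unnamed T-marker clusters counted, T cells were at 3.9, 9.58 and 5.69. Median-of-ratios scaling gave Il1b 0.54 and 0.67 in neutrophils over naive and 1.48, 1.0 and −0.46 in mononuclear phagocytes, and C1qbp 1.28, 0.92 and −0.35 there. With the B cell level subtracted, Il1b was 0.25 on day 2 over naive and 0.24 on day 6 over day 2 in neutrophils, and 0.46, 0.74 and 0.29 (reversed) in mononuclear phagocytes. C1qbp was then 0.51, 2.11 and 1.6 (reversed) in mononuclear phagocytes and −0.38 in T cells on day 6 over naive, reversed from 0.31. Of 27 ratios tried with this subtraction, 11 gave no value, the C1qbp ratios of neutrophils among them. The subtraction was by CPM, whereas free RNA would add a like number of UMIs per cell. It therefore takes too much from classes deeper than B cells, such as mononuclear phagocytes. In macrophage clusters alone, Il1b was 0.66 on day 6 over naive and −0.48 on day 6 over day 2, and C1qbp 1.02 on day 2.

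Of the 10 genes named per comparison and class, those still named with no minimum CPM were 6 for day 6 over naive and 2 for day 6 over day 2 in neutrophils, 2, 3 and 0 in mononuclear phagocytes and 2, 2 and 0 in T cells. With separate clustering 5, 4 and 6 stayed named in T cells, with T-marker clusters counted 6 and 5 over naive, and in macrophage clusters alone 6 in mononuclear phagocytes on day 2. Depth limits the neutrophil values, with 449 naive cells and 20 naive C1qbp UMIs, and those of classes with fewer cells, such as NK with 136 on day 6 and tubule with 97 on day 2.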

Other observations

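All results in this part were examined after the main comparisons, except that the test of Il1b by C1qbp transcript was set before its result was seen. Il1b CPM was also higher in other classes, some of few cells, but free RNA or remaining doublets were not excluded as sources there. In plasmacytoid dendritic cells it was 55.5 CPM in naive, 177 on day 2 and 602 on day 6 (10.9-fold above naive, 8.79 to 13.5), and in NK cells 78.2, 84.2 and 375 CPM (4.79-fold on day 6, 3.84 to 6.03). B cells, the background class, stood at 42.5, 441 and 129 CPM, 10.4-fold (8.78 to 12.3) higher on day 2 and 3.03-fold (2.49 to 3.67) higher on day 6 than in naive kidney. By CPM the levels in plasmacytoid dendritic cells and NK cells thus lay below the B cell level on day 2, and on day 6 above it. On day 2 plasmacytoid cells were deeper than B cells (median 6532 against 2859 UMIs). They held 80 Il1b UMIs in 54 cells, against 350 in 237 B cells, so per cell they were not below B cells. T cells held less Il1b than B cells on day 2, at 91 CPM, so B cells were not the lowest background. By CPM plasmacytoid dendritic cells lay above this T cell level on day 2 and NK cells below it.

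The median of the stress list on day 2 was −1.16 in cDC2 (7 of 12 genes at least 2-fold lower), −1.03 in plasmacytoid dendritic cells (6 lower, 1 higher), −0.98 in plasma cells (4 lower), −0.84 in NK cells (7), −0.72 in tubule cells (4), −0.43 in cDC1 (4) and −0.14 in B cells (4).

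The series title led to the hypothesis that cells with a C1qbp UMI hold less Il1b mRNA than other cells of their cluster and library. It would need a median log2 ratio below −0.2 with at least 3 in 4 ratios below 0, and was tested in mononuclear phagocytes thinned to 3000 UMIs, in 18 combinations of cluster and library with at least 20 cells on each side. The median log2 ratio was −0.1, with 13 values below 0, 6 intervals below 0 and 1 above 0, and a range of −0.97 to 0.33. The lowest was in cluster 12 on day 6, at −0.97 (−1.24 to −0.7), cluster 4 on day 2 stood at −0.75 (−0.84 to −0.66), and the highest was in cluster 2 on day 6, at 0.33 (0.19 to 0.48). All day 2 ratios lay below 0, from −0.75 to −0.06. Those of naive kidney went from −0.34 to 0.28 and those of day 6 from −0.97 to 0.33. This split by library was not part of the test. As the median missed −0.2 and 13 of 18 fell short of 3 in 4, the test left the hypothesis undecided. Its intervals treat UMIs as independent and leave out variation between cells, so they are too narrow for comparing cells. The test measured mRNA, not protein.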
